A study of Homo sapiens with 4 samples.

How the data were processed

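RNA bound by LARP6 was measured by RNA immunoprecipitation followed by sequencing (iRIP-seq) in MDA-MB-231, a human triple negative breast cancer cell line, made to overexpress LARP6, per the labels. The 4 samples were 2 LARP6 immunoprecipitates (IP) and 2 inputs, which are the RNA of the lysate without immunoprecipitation. Libraries were made with a KAPA RNA Hyper Prep kit and read as 150 nt pairs, per the labels' protocols. HISAT2 and HOMER are named in the submitters' processing notes with the build GRCh38, without versions or roles. The peak caller and its settings were not given in the sources used here.

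The authors deposited 1 peak list per IP replicate, so peaks were called separately in each replicate. Per the file headers, each peak carries a position, a strand, a gene, an annotation class and the fraction of its length in each part of a gene. The deposited read counts are whole numbers of IP and of input reads per peak. The deposited RPKM values are reads scaled by peak length and by the library's read total, for the IP and for the input. The authors' log2 fold equals log2 of the IP RPKM plus 1 over the input RPKM plus 1, which was checked in every row and held to within 2.31e-14. The pseudocount of 1 RPKM lets narrow peaks without input reads reach very high folds, so ranks by fold favour them. The deposited p-value has no stated test in the sources used here and was used only to describe and filter peaks within a list. The deposited height score is named as a maximum depth. It can exceed the IP reads of its peak, as at the middle LARP6 peak of replicate 1 with 474 IP reads and a height of 2655. Heights and deposited reads were thus not counted alike, and how they differ is not stated in the sources used here. All folds and intervals below rest on the deposited reads and RPKM values. No column was left unmatched to its sample.

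The lists hold only peaks with at least 10 IP reads and a log2 fold above 1, as the lowest values were 10 reads and 1.00 in both. A gene absent from a list therefore has no measured level. The read totals behind the RPKM values were recovered from reads, width and RPKM. They were 625658 for IP replicate 1, 860337 for IP replicate 2, 1056168 for input replicate 1 and 1005648 for input replicate 2. At these totals 1 read in a peak of 1 kb was worth 1.60, 1.16, 0.947 and 0.994 RPKM. The median peak held 17 IP and 9 input reads in replicate 1, and 15 and 6 in replicate 2. Folds per peak are given as the ratio of RPKM values with an exact conditional binomial 95% interval of the reads. For peaks without input reads the fold is a lower bound against a floor of 3 input counts per library. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No label says whether replicates came from separate cultures, so the spread between them may be technical.

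Both inputs were compared over shared peaks that covered at least 50% of each other and held at least 10 reads. Over 220 peaks the input reads differed by no more than sampling noise (chi-square 246 on 219 degrees of freedom, p = 0.0990). The IP reads of such peaks differed far beyond it (290 peaks, chi-square 1183 on 289 degrees of freedom, p = 2.49e-108), and still did when thinned to the input's depth (231 peaks, p = 3.47e-25). The inputs may therefore be 1 library sequenced or split into parts, which this test cannot tell from 2 separate inputs that differ little. They were counted as 1 sample, while n = 2 below refers to the IPs. Each fold kept the input columns of its own list.

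Peaks were called shared when they overlapped by at least 1 bp on the same strand. Shares have exact Clopper-Pearson 95% intervals. Sharing was tested with a one-sided test against 10000 random placements of replicate 2 peaks inside the RefSeq span of the gene that held them. That span includes introns, so this comparison is easy to exceed for peaks in exons. A gene was counted as having a peak when an exon or intron peak lay on its strand. Gene overlap was tested with two-sided Fisher's exact tests over 19974 protein-coding genes of the RefSeq annotation of GRCh38.p14, with genes matched by symbol and then by unique synonym. In replicate 1, 466 of 496 gene-strand peaks matched a RefSeq gene, and in replicate 2, 673 of 710 did. The background could not be limited to expressed genes, because no expression values were used here, so every gene list enrichment includes the effect of which genes are expressed in these cells.

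The 20 gene lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Each list was tested with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. The mitochondrial list had 1 member in the background and was not testable. The rule names LARP6 and the collagen genes COL1A1, COL1A2 and COL3A1. It adds the 20 genes with the best shared peaks, ranked by fold and taking the worse of both ranks, up to 4 members per list with peaks in both replicates, and the 5 best ranked genes per replicate without any peak in the other. Correlations over shared peaks have permutation p-values from 100000 resamples. Peaks are not independent replicates. The r expected without any difference in fold between peaks was simulated after seeing the data, with IP reads drawn around 1 constant fold over a rate drawn from the pooled input reads.

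No test of IP against input across libraries was made, because each list holds only peaks chosen for a high IP signal. Motif enrichment, annotation of peak midpoints and class shares of shuffled peaks need a genome sequence or exon positions and were not run. Alternatives covered the overlap rule, stricter p-values, the denominator, the background, gene length, each IP replicate left out and, chosen after seeing the data, weighting by bases, a read minimum, the rRNA repeats left out, genes of at most 5 kb, LARP6 left out of its list, an exact binomial test of reads and pooled inputs.

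The tests were checked on simulated data. With 200 changed peaks, the exact binomial test of reads recovered 19.4% of 2-fold, 71.6% of 4-fold and 87.9% of 8-fold changes over the 632 peaks of replicate 1, with 0 calls among 432 unchanged peaks. Over the 835 peaks of replicate 2 it recovered 14.9%, 70.1% and 90.9%, with 0 calls among 635. With 190 random genes as the genes with peaks, 2 of 100 sets called any list. Randomly placed peaks passed the shuffle test at 0.05 in 2 of 20 runs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.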

Results

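The RNA that came down with LARP6, an RNA-binding protein of the La-related family, was profiled in MDA-MB-231 cells that overexpress it. The stated purpose was to find the RNA targets of LARP6 in triple negative breast cancer and to relate them to splicing. In IP replicate 1, 632 peaks stood above the input, and in IP replicate 2, 835 peaks did. Gene-strand peaks fell on 400 gene symbols in replicate 1 and on 566 in replicate 2, of which 237 were in both. Listed peaks held 5.37% of the 625658 IP reads of replicate 1 and 1.33% of its 1056168 input reads. In replicate 2 they held 5.66% of 860337 IP reads and 1.63% of 1005648 input reads. The inputs differed by no more than sampling noise (chi-square p = 0.0990) and were counted as 1 sample.

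LARP6 RNA itself was pulled down in both replicates. The gene, on the minus strand of chromosome 15 from 70829130 to 70854157 (GRCh38), held 3 gene-strand peaks in each list, all at least 93% coding sequence. The peak nearest the 5' end (70853886 to 70854101 in replicate 1, 93% coding sequence and 6% 5' UTR) had a log2 fold of 2.96 ± 0.13 (SD, n = 2). Its fold over input was 8.27 (95% interval 7.40 to 9.25) in replicate 1 and 7.28 (6.50 to 8.17) in replicate 2. The middle peak (70836370 to 70836510, 96% coding) reached 6.30-fold (5.17 to 7.73) and 6.65-fold (5.54 to 8.04). The widest peak (70832054 to 70833124, 99% coding) reached 5.01-fold (4.50 to 5.60) and 5.08-fold (4.59 to 5.64). Together these peaks held 0.586% and 0.578% of all IP reads, against 0.0902% and 0.0944% of the input reads. No LARP6 peak contained 3' UTR sequence in either list, and the 2921 bp between the 3' end of the gene and the first peak held none. Peaks on the opposite strand mirrored all 3 positions in both replicates, with 1064 against 3666 IP reads in replicate 1 and 1207 against 4974 in replicate 2. Among them, the peak listed under an intron of LRRC49 (70853889 to 70854099, plus strand, log2 fold 3.34 ± 0.38, SD, n = 2) lies opposite the 5' LARP6 peak.

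**Figure D1:**
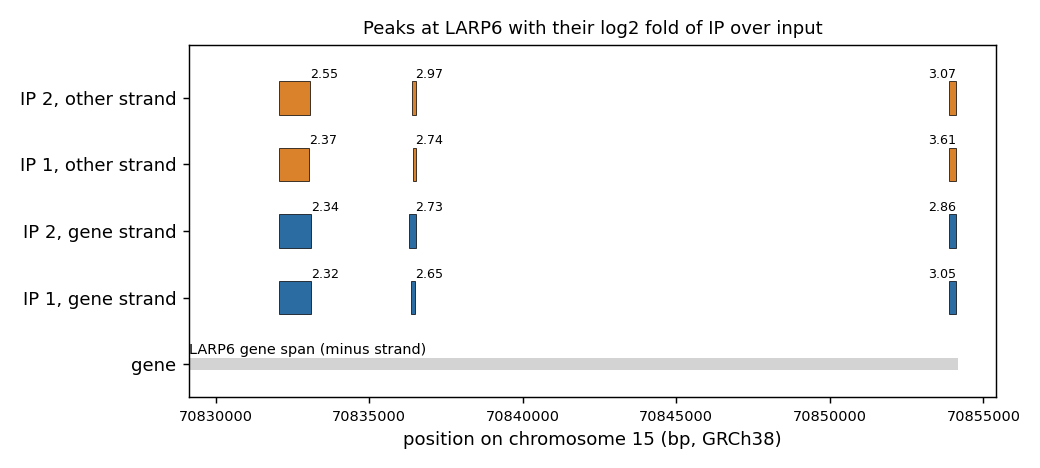
Peaks at the LARP6 gene on chromosome 15 (x axis, bp, GRCh38), by IP replicate and strand (rows). Bars are drawn to scale and the numbers are log2 folds of IP over input. Gene-strand values run from 2.32 to 3.05, and each peak has a counterpart on the other strand.

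Type I and type III collagen mRNAs, which are textbook ligands of LARP6 in collagen-producing cells, were not among the peaks. COL1A1, COL1A2 and COL3A1 had 0 peaks in either list. None of the 25 fixed collagen genes had a peak in either replicate. Because the lists keep only peaks with at least 10 IP reads, this does not measure whether these mRNAs were expressed or bound at a lower level.

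Ribosomal RNA sequences gave a large part of the reads in peaks. The block of rRNA repeats on the short arm of chromosome 21 held 68 peaks in replicate 1 and 66 in replicate 2, with 38.1% and 40.0% of all IP reads in listed peaks. On the rRNA strand of the 3 annotated 45S units, 17 of 19 peaks in replicate 1 lay in the spacers of the precursor and not in mature rRNA, and 21 of 22 did in replicate 2. Spacers make up 46.8% of the annotated unit length. The lists keep only peaks with a log2 fold above 1 over input, so parts of the unit without a peak have no measured level. The 5' external transcribed spacer alone held 14 and 15 of these peaks, with a median log2 fold of 2.92 in replicate 1 and 2.96 in replicate 2. No rRNA-strand peak lay mostly in 18S or 5.8S rRNA. The opposite strand of the units held more peaks, 32 and 26, of which 16 and 15 lay in spacers and 12 and 9 in 28S rRNA. The units are near-identical copies, so reads cannot be assigned to 1 unit, peaks in different units are not independent and no test was made. A 28S peak on the rRNA strand (8217220 to 8217375) with 681 IP and 6 input reads in replicate 1 had no counterpart on that strand of the unit in replicate 2. On the opposite strand a peak at this place was shared, with 72 IP and 1 input reads in replicate 1 and 147 and 0 in replicate 2.

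**Figure D2:**
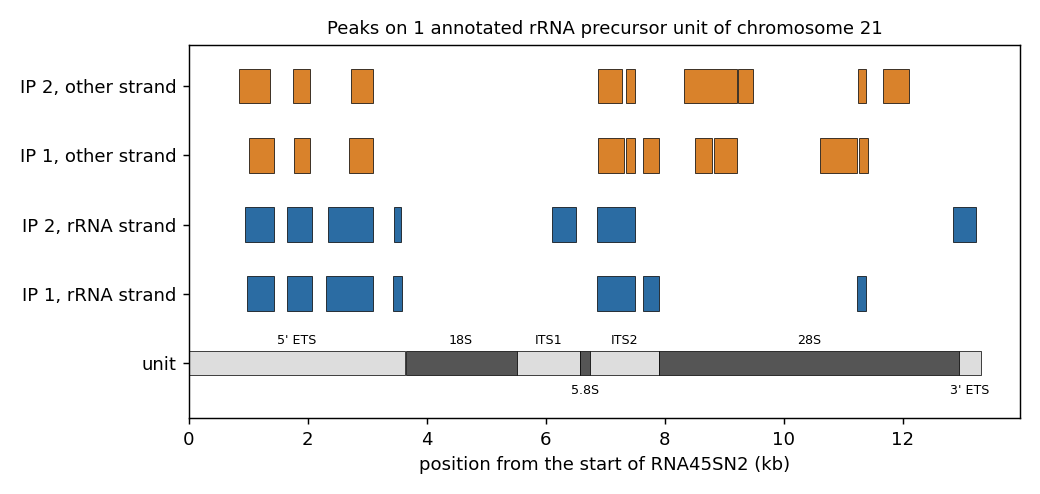
Peaks on RNA45SN2, 1 of the 3 annotated rRNA precursor units of chromosome 21, by IP replicate and strand (rows). The x axis is the distance from the start of the unit in kb, and dark segments of the bottom row are mature rRNAs. In both replicates most rRNA-strand peaks lie in the 5' external spacer and the second internal spacer.

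5S ribosomal RNA genes and pseudogenes formed a second rRNA group. They held 30 peaks in replicate 1 and 21 in replicate 2, with a median log2 fold of 2.96 and 2.27. In replicate 2, 21 of the 21 overlapped a replicate 1 peak. RNA5S6 (chromosome 1, 228621448 to 228621563) reached 13.9-fold (95% interval 6.67 to 33.6) and 6.08-fold (3.06 to 13.4). The pseudogene RNA5SP74 (chromosome 1, 204562417 to 204562487) had 55 IP and 3 input reads in replicate 1 and 33 and 2 in replicate 2. 5S copies are near-identical as well, so the assignment to single genes is uncertain. Small nucleolar RNA genes held 6 and 11 peaks, and 6 of them were shared in each list.

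The genes with the best ranked shared peaks were mostly such noncoding RNAs, besides a few mRNAs. An intron peak of ANKRD30BL (chromosome 2, 132255502 to 132255622, minus strand) ranked highest, with 36 and 84 IP reads and no input read, at least 20.3-fold and 32.7-fold above a floor of 3 input counts (exact lower 95% bounds 15.6 and 26). An intron peak of a lncRNA (chromosome 8, 70851388 to 70851618) was at least 7.88-fold and 7.01-fold above that floor (exact lower bounds 5.6 and 5.14). Among the top 20 were RNA5SP336, RNA5SP242, RNA5S5, RNA5S3, RNA5S1, the gene labelled 5S_rRNA on chromosome X, MIR663AHG, LARP6 and LRRC49. CH507-513H4.1 and CH507-528H12.1, 2 lncRNA names whose introns overlap the chromosome 21 rRNA units, were there as well.

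Of the protein-coding genes in that group, 4 had their best shared peak in the 5' UTR. EGR1, an immediate-early transcription factor (chromosome 5, 138465495 to 138465665), had a log2 fold of 4.01 ± 0.30 (SD, n = 2), with 13 and 14 IP reads against 1 input read in each replicate. Its folds had wide intervals, 21.9 (95% interval 3.30 to 932.6) and 16.4 (2.49 to 692.0). GADD45A, a stress-induced growth regulator (chromosome 1, 67685253 to 67685418), reached 9.45-fold (95% interval 3.6 to 31.4) and 7.60-fold (2.64 to 30). TLE5, a transcriptional corepressor (chromosome 19, 3062176 to 3062466), reached 10.6-fold (3.64 to 41.7) and 16.4-fold (4.13 to 141.8). CEP55, a cytokinesis protein (chromosome 10, 93496625 to 93496890), reached 11-fold (2.48 to 100.2) and 6.42-fold (1.40 to 59.7). KIF1C, a kinesin motor, held 7 peaks in replicate 1 and 9 in replicate 2, spread over coding sequence and both UTRs. Its best shared peak (chromosome 17, 5007468 to 5007548, coding) had a log2 fold of 4.0 ± 0.04 (SD, n = 2) from 10 and 15 IP reads against 1 input read in each. The small SD does not show precision, as the folds were 16.9 (95% interval 2.40 to 732.6) and 17.5 (2.70 to 738.1).

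Sharing between replicates followed read number. Of the 632 peaks of replicate 1, 338 (53.5%, 95% interval 49.5 to 57.4) overlapped a replicate 2 peak. Of the 835 peaks of replicate 2, 328 (39.3%, 36.0 to 42.7) overlapped a replicate 1 peak. Among replicate 1 peaks with 10 to 12 IP reads 34.7% (28.1 to 41.7) were shared, and among those with over 50 reads 79.2% (70.0 to 86.6). In replicate 2 the same classes had 16.3% (12 to 21.4) and 81.0% (72.7 to 87.7). The weakest class held 202 and 257 peaks, and differences between replicates were not tested for them. Among peaks inside RefSeq genes, 231 of 484 were shared, against a mean of 51.8 after random placement in the same genes (permutation test, p = 0.0001, the smallest 10000 placements can give). In genes of at most 5 kb, a test chosen after seeing the data, 68 of 132 were shared against a mean of 36.5 (permutation test, p = 0.0001).

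Protein-coding genes were shared far more often than chance. Of 335 genes in replicate 1 and 498 in replicate 2, 190 had peaks in both, against 8.35 expected from 19974 genes (22.7 times, two-sided Fisher's exact test, p = 6.66e-226). For 159 of them, the peaks themselves overlapped. The background includes genes that these cells may not express.

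Log2 folds of overlapping peaks correlated between the replicates. Over 325 pairs of shared peaks the log2 folds had Pearson's r = 0.68 and Spearman's rho = 0.59 across peaks (permutation p = 1e-05 each, the smallest 100000 resamples can give, 2 measures computed). Both folds of a pair rest on inputs counted as 1 sample, which can itself give a correlation. In 1000 simulations of IPs with 1 constant fold over these inputs, with counting noise only, r had a mean of 0.0842 and reached at most 0.398. The median SD between replicates was 0.29 on the log2 scale. In 266 of the 325 pairs both lower 95% bounds of the fold were above 1. Median peak width was 281 bp (quartiles 176 to 426) in replicate 1 and 331 bp (221 to 481) in replicate 2. Median height score was 24 (17 to 44) and 23 (16 to 40). The median log2 fold was 1.72 (1.27 to 2.43) and 1.59 (1.25 to 2.07). After Benjamini-Hochberg adjustment of the authors' p-values within each list, 501 of 632 and 522 of 835 peaks had values under 0.05. The lists keep only peaks with at least 10 IP reads and a log2 fold above 1. These counts and the 266 pairs are therefore in large part fixed by that choice. Adjustment over the kept peaks alone does not control the false discovery rate of the peak calling.

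**Figure D3:**
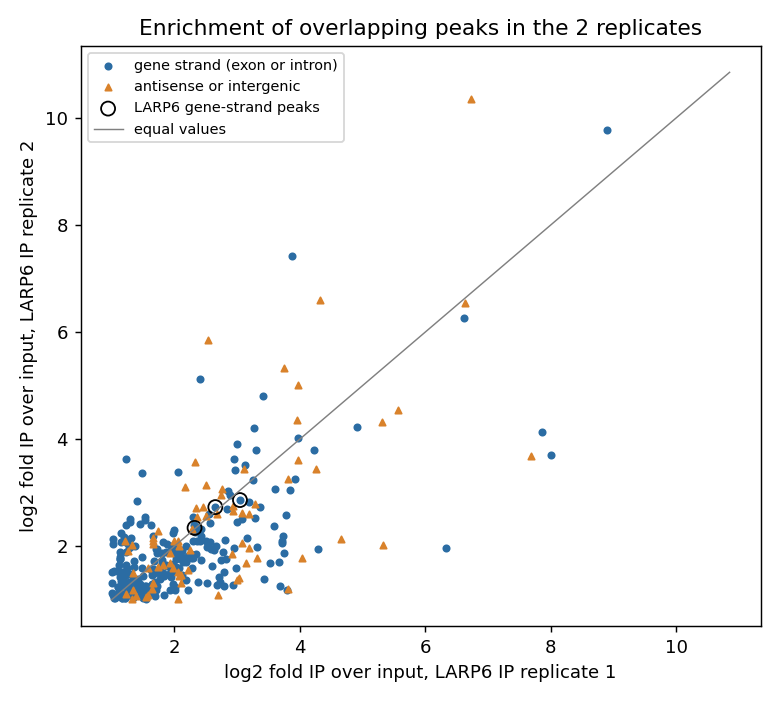
Log2 fold of IP over input of 325 overlapping peaks in IP replicate 1 (x axis) and IP replicate 2 (y axis). Each point is a pair of peaks, circles mark gene-strand LARP6 peaks, and the line marks equal values. Pearson's r is 0.68, and the LARP6 peaks lie close to the line.

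Peaks lay mainly in exons of protein-coding genes, and coding sequence was the most frequent part. By the part that held most of its length, 202 of 632 peaks in replicate 1 (32.0%, 95% interval 28.3 to 35.8) and 296 of 835 in replicate 2 (35.4%, 32.2 to 38.8) were coding sequence. The 5' UTR held 19.3% (16.3 to 22.6) and 20.5% (17.8 to 23.4), and the 3' UTR 8.39% (6.34 to 10.8) and 9.94% (8.0 to 12.2). Introns held 11.2% (8.88 to 14) and 13.5% (11.3 to 16), noncoding exons 7.59% (5.65 to 9.94) and 5.63% (4.16 to 7.42). By the deposited annotation class, introns held 6.01% and 7.07%, because 33 and 54 peaks of the exon class lay mostly in introns. Intergenic peaks were 4.59% (3.09 to 6.52) and 3.23% (2.14 to 4.67). In 143 and 211 peaks both 5' UTR and coding sequence were present. Antisense peaks were 16.9% (14.1 to 20.1) in replicate 1 and 11.7% (9.63 to 14.1) in replicate 2, the only class of the 7 that differed between the replicates (Fisher's exact test, adjusted p = 0.0342). That test compares 1 library with 1 library and counts peaks as independent. Of the antisense peaks, 28 and 24 lay in the chromosome 21 rRNA repeats, where peaks are not independent. The lengths of these parts in expressed transcripts were not used here, so the shares do not show enrichment over transcript composition.

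**Figure D4:**
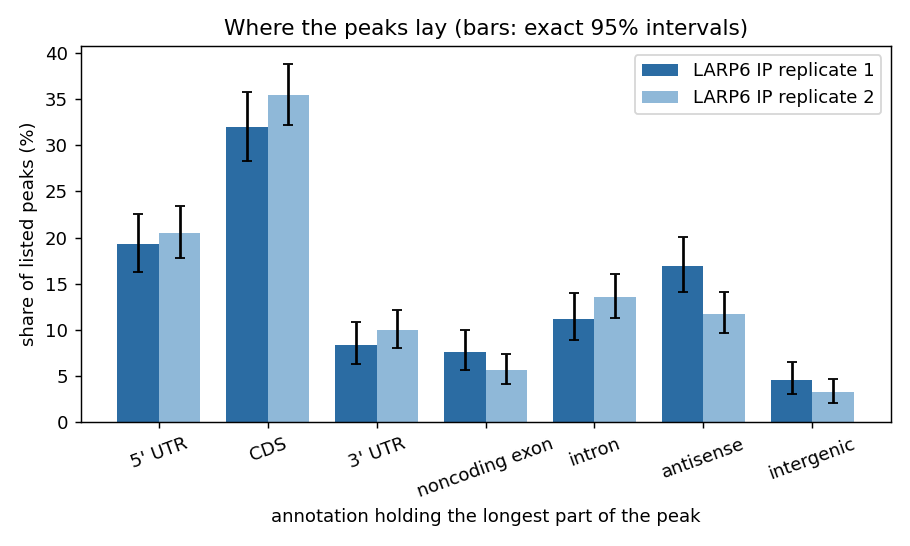
Share of listed peaks (y axis, %) by the annotation that holds the longest part of each peak (x axis), in both IP replicates. Bars start at 0 and error bars are exact 95% intervals. Coding sequence is highest with 32.0% and 35.4%, followed by the 5' UTR.

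Genes of the translation machinery and of abundant housekeeping mRNAs were over-represented among the genes with peaks in both replicates, against all protein-coding genes. A listed peak needs at least 10 IP reads, which favours abundant mRNAs, and the background includes genes these cells may not express. Such an excess can therefore arise from abundance alone, here and for the lists below. Of 78 cytosolic ribosomal protein genes, 7 had peaks in both (9.43 times expected, Fisher's exact test, adjusted p = 0.000189), namely RPL3, RPL13, RPL13A, RPL27A, RPL28, RPL32 and RPS2. RPL27A (chromosome 11, 8684234 to 8684359, mostly 5' UTR, the rest noncoding exon) reached 3.30-fold (95% interval 1.93 to 5.79) and 3.90-fold (2.0 to 8.16). RPS2 (chromosome 16, 1962974 to 1963099, noncoding exon) reached 2.64-fold (1.85 to 3.81) and 2.18-fold (1.59 to 3.03). Replicate 1 held no other RPS2 peak, and the RPS2 peaks of replicate 2 in coding sequence were not shared. So no coding or UTR peak of RPS2 was in both lists. For RPL13 (chromosome 16, 89561580 to 89561755), RPL13A and RPL28 the interval of the best shared peak reached below 1 in 1 replicate each, for RPL13 from 0.937 to 4.70. RPL3 and RPL32 peaks lay at different positions in the replicates, and the RPL3 intervals reached below 1 in both. Of 37 abundant housekeeping mRNAs, 5 had peaks in both (14.2 times expected, Fisher's exact test, adjusted p = 0.000252), namely ALDOA, FTH1, FTL, S100A11 and YWHAZ. The interval of the shared ALDOA peak, in an intron, reached below 1 in replicate 1 (2.06-fold, 0.777 to 5.63), the YWHAZ peak, over intron and 5' UTR, had a lower bound of 1.04 in replicate 2, and the S100A11 peaks lay apart. The shared peaks of the ferritin mRNAs lay mostly in the 5' UTR, where these mRNAs are known to carry an iron-responsive element, and FTH1 had 2 more peaks in replicate 2, mostly coding sequence. FTL (chromosome 19, 48965313 to 48965613) reached 3.45-fold (2.40 to 5.02) and 2.94-fold (2.06 to 4.24). FTH1 (chromosome 11, 61967310 to 61967625) reached 3.14-fold (2.44 to 4.05) and 2.45-fold (1.94 to 3.11).

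Of 37 translation factors, EIF1, EIF5 and EIF5A had peaks in both replicates (8.52 times expected, Fisher's exact test, adjusted p = 0.0259), with their shared peaks at the 5' UTR in replicate 1. EIF1 (chromosome 17, 41688896 to 41689076) reached 3.62-fold (1.39 to 10.5) and 4.44-fold (1.60 to 15.2). For EIF5 the interval reached below 1 in both. The call for the list was lost among the 50% of peaks with the lowest p-values, where fewer genes remained and the fold was 6.66 (exact test, adjusted p = 0.375, from 0.00181 to 0.375 over the alternatives). Of 40 cytoskeleton genes, PFN1, PLEC and TMSB10 had peaks in both (7.88 times expected, Fisher's exact test, adjusted p = 0.0259). The call was lost when the peaks themselves had to overlap, at 6.28 times expected (exact test, adjusted p = 0.161), since TMSB10 peaks lay apart, and the alternatives ran from 3.17e-06 to 0.161. PLEC, which encodes the linker protein plectin, held a coding peak of 3901 bp (chromosome 8, 143922476 to 143926376) with 1688 IP reads at 4.01-fold (3.67 to 4.39) in replicate 1 and 2914 at 4.94-fold (4.54 to 5.37) in replicate 2. PFN1, encoding the actin-binding profilin (chromosome 17, 4948265 to 4948560), reached 4.99-fold (3.03 to 8.50) and 4.33-fold (2.61 to 7.48).

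Of 7 LARP family genes, LARP6 and LARP1 had peaks in both replicates (30 times expected, Fisher's exact test, adjusted p = 0.0122). Without LARP6, which is overexpressed here, a test chosen after seeing the data, LARP1 alone remained, 17.5 times expected, and the list did not pass (exact test, adjusted p = 0.186, from 6.29e-05 to 0.186 over the alternatives). LARP1, a regulator of ribosomal protein mRNA translation (chromosome 5, 154755996 to 154756201, coding), reached 2.89-fold (1.44 to 6.05) and 2.17-fold (1.46 to 3.25).

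Genes for splicing, the matrix and breast cancer did not pass among genes with peaks in both replicates. Of 54 splicing factors, 0 had peaks in both replicates, with 5 in replicate 1 (5.52 times expected, exact test, adjusted p = 0.00831) and 3 in replicate 2 (adjusted p = 0.337). Extracellular matrix and adhesion genes had 0 of 35, collagen folding and modification 0 of 27, apoptosis 0 of 34, DNA damage repair 0 of 38 and replication-dependent histones 0 of 54. In single replicates the histones had 1 gene with a peak in replicate 1 and 6 in replicate 2 (exact test, adjusted p = 0.00624 in replicate 2), and each of the other 4 lists had at most 1. Of 35 breast cancer oncogenes and suppressors 2 had peaks in both (exact test, adjusted p = 0.145, 0.0436 before adjustment), CCND1 and HMGA1. In single replicates that list had 4 and 5 genes (exact test, adjusted p = 0.00900 and 0.00624). CCND1, encoding cyclin D1 (chromosome 11, 69641187 to 69641517, coding and 5' UTR), reached 3.90-fold (1.97 to 8.14) and 2.89-fold (1.61 to 5.41), and was the 1 of 40 cell cycle genes in both. HMGA1 peaks lay in the 3' UTR in replicate 1 and in coding sequence in replicate 2. CAVIN1 was the 1 of 26 mesenchymal genes and KRT7 the 1 of 25 luminal and epithelial markers (exact test, adjusted p = 0.489 each), both with peaks at different positions. SNHG12 was the 1 of 28 nuclear and small noncoding RNAs (exact test, adjusted p = 0.293). The comparison lists of 26 liver-secreted and 26 long neuronal genes had 0 in either replicate. In all, 5 of 20 lists passed after adjustment and 6 before it. With under 1 gene expected per list, an absence was not detectable as depletion.

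The best ranked genes with peaks in only 1 list rested on few reads, and the ranking by fold favours such peaks. In replicate 1 the best ranked were UBTD1, RNA5S15, TJP1, ZCCHC3 and PITPNM3, with 13, 15, 10, 10 and 20 IP reads. In replicate 2 they were NSUN6, ATF3, CCT6A, ASPHD1 and CTXN1, with 15, 10, 10, 10 and 10 IP reads and no input read. TJP1, encoding a tight junction protein (chromosome 15, 29822142 to 29822452, 5' UTR), had 1 input read, a fold of 16.9 (95% interval 2.40 to 732.6). ATF3, a stress-induced transcription factor (chromosome 1, 212608783 to 212608993, mostly 5' UTR), was at least 3.90-fold above the floor of 3 input counts (exact lower bound 2.62). Their absence from the other list was not tested as a difference.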

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

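The tests in this part were all chosen after the results were seen. Antisense and intergenic peaks stand outside the gene comparisons. The lists keep only peaks with a log2 fold above 1, so the counts above input that follow are in large part fixed by that choice. In LARP6 IP replicate 1, 99 of 107 antisense peaks and 27 of 29 intergenic peaks had a lower 95% bound of the fold above 1. In replicate 2, 79 of 98 antisense peaks and 21 of 27 intergenic peaks did. Of the intergenic peaks, 16 in each replicate lay in the chromosome 21 block of rRNA repeats, and so did 28 and 24 of the antisense peaks. The replicates shared 60 of 107 and 58 of 98 antisense peaks.

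Antisense peaks often overlapped gene-strand peaks on the other strand, as at LARP6. Antisense RNA placed at random along the whole span of the same genes is argued against. In replicate 1, 57.1% of 70 antisense peaks lay opposite a peak, against at most 20% in 1000 random placements. In replicate 2, 62.7% did, against at most 23.7%. The span includes introns, so this comparison is easy to exceed for peaks in exons. Antisense RNA placed at random within exons was not tested. Reads put on the wrong strand at 1 constant rate were examined by the scatter of the reads of such pairs. Over pairs outside the chromosome 21 rRNA repeats that covered at least 80% of each other, the reads scattered around 1 rate with a dispersion (chi-square over degrees of freedom) of 9.58 in replicate 1 (21 pairs) and 23.4 in replicate 2 (17 pairs). Counts simulated at 1 rate with counting noise only, cut at 10 reads as the lists are, gave at most 3.65 and 5.53 in 1000 runs. Without LARP6 the dispersion was 4.52 and 24, against at most 2.79 and 3.75 in simulated counts. The simulation left out duplicate reads and the fold cutoff of the lists. IP reads of matched peaks differed between replicates with a dispersion of 4.09. That value compares 2 libraries, so it does not set the scatter of strand ratios inside 1 library. The scatter thus exceeded counting noise in both replicates. At LARP6 in replicate 1, the opposite strand had 0.184 of the gene-strand RPKM at the widest peak and 0.388 at the 5' peak. In replicate 2 these ratios were 0.162 and 0.345, so the difference recurred. These values argue against 1 constant rate as the only source of the antisense reads in these pairs. A leak at a rate that varies between sequences stays open, as does a leak at 1 rate beside other sources. So do antisense RNA within exons and double-stranded RNA at these positions, and the design tests no biological explanation.

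LARP6 peaks lay mostly in its coding sequence and held no 3' UTR. Transcripts of an introduced LARP6 sequence that holds the coding region could give this pattern, since the lowest coding share among the 6 gene-strand peaks was 93%, but the labels do not describe the sequence. Double-stranded DNA of such a sequence in the libraries is argued against as the whole signal. Over both inputs the antisense to gene-strand ratio in these peaks was 0.205, and the highest upper 95% bound in a single input was 0.248, where DNA would give about equal strands. Binding of LARP6 protein to its own mRNA was not tested, because all cells overexpressed LARP6 and no IP with another antibody was analysed here.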

How the results depend on the processing

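Of 88 alternative values, 67 kept their call or stayed within the replicate spread, the interval or 1.5 times the count, 18 moved, 3 lost their call and 0 reversed. The share of replicate 1 peaks with a counterpart became 46.4% at a reciprocal overlap of 50%, 63.6% in the 50% of each list with the lowest p-values, 39.3% with replicate 2 as denominator and 75.4% for peaks with at least 20 IP reads, the last chosen after seeing the data. Among the 50% with the lowest p-values, mean class shares became 26.7% for coding sequence, 6.33% for 3' UTR, 9.61% for noncoding exons, 19.4% for antisense and 4.92% for intergenic peaks. The median height score became 36.5 and the median log2 fold 2.18. Over shared peaks these medians were 33.5 and 1.86. Weighted by bases, chosen after seeing the data, shares were 18.8% for 5' UTR, 37.9% for coding sequence, 10.7% for 3' UTR, 4.09% for noncoding exons. That 50% holds stronger peaks by construction, and otherwise the cause was not tested. With genes of 1 replicate alone, 7 to 9 lists passed in place of 5, the added lists being mesenchymal, luminal, breast cancer and splicing genes in replicate 1 and breast cancer genes and histones in replicate 2. Gene overlap was 21.1 times expected within deciles of gene length. It was 56.0 times in the 50% of each list with the lowest p-values, and 63.1 times with all annotated genes as background. The correlation of folds was 0.70 at a reciprocal overlap of 50% and 0.93 for log2 heights. Depth as a cause was not tested. No paired analysis was possible because each list holds only peaks chosen for its own IP signal and the inputs count as 1 sample; the exact binomial test of reads, chosen after seeing the data, ran within each replicate. Motif alternatives, midpoint annotation and shuffled class shares were not run without a genome sequence.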

Other observations

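The list and tests in this part were chosen after gene names with peaks had been seen. Immediate-early genes, short genes switched on within minutes of a stimulus, recurred among the peaks. Of 55 such genes in a list written from general knowledge, 15 had peaks in both replicates, 20 in replicate 1 and 19 in replicate 2. Those in both were BHLHE40, CCN1, CCN2, DUSP1, EGR1, FOSL1, FOSL2, GADD45A, IER2, IER3, IER5, JUN, JUND, MAFF and NFKBIA. JUND, an AP-1 subunit (chromosome 19, 18280468 to 18281613, mostly coding sequence), had a log2 fold of 2.05 ± 0.29 (SD, n = 2). JUN (chromosome 1, 58783678 to 58783898, 5' UTR) had 1.94 ± 0.11 (SD, n = 2). CCN1, a secreted matrix protein (chromosome 1, 85580769 to 85580979, 5' UTR), had 1.69 ± 0.37 (SD, n = 2), with 69 and 90 IP reads. DUSP1, a phosphatase of MAP kinases, had 1.66 ± 0.23 (SD, n = 2), and IER2 1.38 ± 0.31 (SD, n = 2). FOSL2, CCN2, BHLHE40 and NFKBIA each had a peak whose lower 95% bound was below 1 in 1 replicate, and the MAFF peaks lay apart.

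A hypothesis is that LARP6 IP favours these short-lived mRNAs beyond what gene length or abundance gives. The count was 28.7 times expected, and 22.1 times the mean of 10000 random lists of the same gene lengths (permutation test, p = 0.0001, the smallest these lists can give), but the list was written after names were seen. That choice inflates such a count, so the test leaves short genes open as a cause. RNA abundance alone stays open too, since 27.3% of immediate-early genes against 13.5% of abundant housekeeping mRNAs had peaks in both replicates (two-sided Fisher's exact test, p = 0.132) and no expression values were used here.

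Protein-coding genes with peaks were shorter than the annotation as a whole, with a median span of 16.5 kb in replicate 1 and 17.9 kb in replicate 2 against 24.2 kb. Chromosome 19, which holds 7.26% of protein-coding genes, held 12.5% of the peaks of replicate 1 and 12.2% of those of replicate 2. These were not compared with the genes expressed in these cells.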
